A study of Mus musculus with 15 samples.

How the data were processed

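RNA of Kupffer cells was measured in 15 libraries of 4 groups: 3 of ob/ob and 4 of wild type mice at 9 weeks, and 4 of ob/ob and 4 of wild type mice at 14 weeks. The genotype label of the wild type mice is C57BL/6J and that of the others ob/ob. Per the labels, RNA was extracted with TRIzol, libraries were made with a TruSeq stranded mRNA kit and sequenced on an Illumina HiSeq instrument. Per the submitters' processing notes, bcl2fastq, cutadapt, STAR and Cufflinks were used with the mouse genome build mm10, with no versions given. The deposited values were FPKM, fragments scaled by transcript length and by the mapped fragments of the library, in a table per age that held 1 value per locus and library. Neither the labels nor the tables state whether the 2 ages were scaled together. Both tables listed the same 15897 loci with no value of 0, so a locus at 0 in any library appears to have been left out by the authors. Each column was matched to its sample by the column name in the labels, and 0 columns were left without a sample. Sequencing lane followed group, with 9 week ob/ob libraries on lane 8, 9 week wild type on lane 7, 14 week ob/ob on lane 6 and 14 week wild type on lane 5.

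Values were analysed as log2(FPKM + 1), which understates the change of genes with low FPKM. Loci with a mean of at least 1 FPKM over the libraries compared were tested. At each age ob/ob was compared with wild type by limma 3.58.1 in R 4.3.3, with an empirical Bayes variance trend and Benjamini-Hochberg adjustment at 0.05, and the difference of the ob/ob effect between ages was tested as an interaction in a joint fit of all 15 libraries. No further scaling was applied to the FPKM. The 14 and 9 week levels within a genotype were not compared. Errors beside log2 changes are standard errors of the fit, and those beside FPKM are SDs over libraries. Gene lists were tested with camera at a preset correlation of 0.01 between genes and again with an estimated correlation, for lists with at least 5 tested members, and list members were also adjusted over the list alone. Lists were also tested with fry, and the difference between ages was tested over lists with camera and with fry. Gene positions were read from GENCODE M21, tables were joined in Python 3.11.15 with numpy 2.4.6, and figures were drawn with matplotlib 3.10.9.

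The comparisons, the 35 gene lists, the alternatives set in advance and the rule for the genes to name were fixed before the data were examined. The lists covered NRF2 and antioxidant genes, inflammatory and interferon genes, lipid, sterol, energy and stress pathways, proliferation, and markers of Kupffer cells, other macrophage states and other cell types of the liver. Of 729 symbols on the lists, 682 were found in the tables, and 865 loci with several overlapping symbols were tested as 1 locus each. Not found, for a reason that is unknown, were Apoe of the LXR list and Cyba of the NADPH oxidase list. Most mitochondrially encoded genes, mt-Co1 and mt-Nd4 among them, were not found either. Per age, the rule named the 8 largest rises and the 8 largest falls among genes past the threshold whose ob/ob and wild type libraries did not overlap, leaving out a locus only where each of its symbols had the name of a predicted gene, a small RNA or a ribosomal pseudogene. It also named 17 genes set in advance (Nfe2l2, Keap1, Gclc, Gclm, Nqo1, Hmox1, Txnrd1, Srxn1, Tnf, Il1b, Ccl2, Igfbp7, Clec4f, Timd4, Gata4, Lep and Lepr), and in each list up to 4 members, those past the threshold with the largest change, else those with the smallest p. Of the 262 gene values that the rule gave, the text describes 186 and the others are not described here. For the difference between ages the rule named the largest past the threshold, of which there were none. Lep is not analysed here.

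Read depth is unknown, since no counts are in the tables: among 3339 loci below 1 FPKM in each library, at most 0.809% of the ratios between 2 libraries fell in any 1 bin of 0.5%, so no step of a single fragment could be read from them, and the precision of low values was not estimated from depth. The steps were tested on simulated data with the spread of these libraries and 200 changed genes. These were drawn from loci with a mean of at least 2 FPKM, so recovery of lower genes was not measured. At 9 weeks 31.3, 77.6 and 93.9% of the genes changed by 1.5-, 2- and 4-fold were recovered, at 14 weeks 35.8, 83.6 and 93.9%, and for the difference between ages 31.3, 67.2 and 93.9%. Of the calls made, 4.26%, 5.96% and 4.48% were false. A list moved by 1.5-fold was called in each of these comparisons, with 0 of 31 other lists. The simulated spread was drawn for each gene on its own, so this does not show how camera behaves on lists of correlated genes. Nor does it show the share of false calls where genes vary together between libraries.

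As alternatives set in advance, the counts were computed again with a pseudocount of 0.1, no filter, a filter at a mean of 5 FPKM, median-ratio scaling, quantile normalization, robust empirical Bayes, library weights, a joint fit of all libraries, the hepatocyte score as a covariate, replicate number as a block, an estimated correlation for lists, and leaving out each library in turn. Chosen after the data were seen were the sinusoidal endothelial score as a covariate, the hepatocyte score as a covariate in a joint fit, leaving out ob/ob library 2 and wild type library 1 at 14 weeks together, leaving out ob/ob libraries 1 and 3 at 9 weeks together, and the camera test of the difference between ages. Libraries were also regrouped, in each possible split at 1 age and in 100 splits for the difference between ages, to count how often as many genes were called.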

Results

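RNA of Kupffer cells, the resident macrophages of the liver, was sequenced from ob/ob mice, which lack functional leptin and become obese, and from wild type mice at 9 and 14 weeks of age. The 15 libraries fell into 4 groups, with 3 ob/ob and 4 wild type libraries at 9 weeks and 4 of each genotype at 14 weeks. Each table held the same 15897 loci, and the FPKM of a library summed to between 528155 and 604530. Read depth is unknown, because the tables hold no counts. The labels do not say that the replicates came from separate animals, so a p-value measures the spread between these libraries, which may be technical.

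Libraries differed in the level of transcripts typical of other liver cells. Alb, the albumin gene of hepatocytes, was 10.7-fold higher in the ob/ob mean than in the wild type mean at 9 weeks and 7.32-fold higher at 14 weeks. The hepatocyte score, the mean log2(FPKM + 1) of the hepatocyte list, was 5.18 ± 0.397 (SD, n = 3) in ob/ob and 3.10 ± 0.266 (SD, n = 4) in wild type libraries at 9 weeks, and 5.16 ± 0.719 against 3.43 ± 0.448 (SD, n = 4 each) at 14 weeks. Of single libraries, ob/ob library 2 at 14 weeks had the highest hepatocyte score (6.23), and the sinusoidal endothelial score was lowest in ob/ob library 3 at 9 weeks (5.62) and was 6.69 in wild type library 1 at 14 weeks. In ob/ob libraries 1 and 3 at 9 weeks, 8 neighbouring X chromosome genes, Tlr7 among them, had a median log2 ratio to the wild type mean of 0.79 and 1.10, against 0.012 in ob/ob library 4.

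The first comparison asked how Kupffer cell RNA of ob/ob mice differed from wild type at 9 weeks. The largest rises of macrophage genes were in 2 of the lipid-associated macrophage list: Gpnmb, a lysosomal glycoprotein of lipid-laden macrophages, reached 53.4 ± 26.0 FPKM (SD, n = 3) against 0.639 ± 0.288 FPKM (SD, n = 4), a log2 change of 4.97 ± 0.28 (SE), and Mmp12, the macrophage elastase, rose by 4.67 ± 0.19. Monocyte genes rose with them, among them Ccr2, the receptor that brings monocytes into tissue (2.19 ± 0.23), and Cx3cr1 (2.06 ± 0.27). The proliferation marker Mki67 rose by 1.22 ± 0.18. Lower in ob/ob libraries were the C-type lectin Cd209f, which fell by 2.62 ± 0.42, the B cell chemoattractant Cxcl13, which fell by 1.88 ± 0.40, and the Kupffer cell folate receptor Folr2, which fell by 0.81 ± 0.15. With the hepatocyte score as a covariate the fall of Cd209f turned to 0.94 ± 0.97 (adjusted p = 0.936) and no longer passed, while Cxcl13 and Folr2 stayed lower and did not pass either (adjusted p = 0.908 and 0.908). Nfe2l2, which encodes NRF2, the activator of antioxidant genes, was at 114 ± 7.94 FPKM (SD, n = 3) against 114 ± 12.6 FPKM (SD, n = 4) and did not pass the test (adjusted p = 0.986).

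By limma, 909 of 11501 genes passed an adjusted p of 0.05, 589 higher and 320 lower in ob/ob (64.8% higher). Under median-ratio scaling 827 passed, 648 higher and 179 lower (78.4% higher). Changes of at least 2-fold were counted in 373 genes that rose and 24 that fell. The count was 409 without ob/ob library 1, 544 without ob/ob library 4, 540 without wild type library 2, 467 without wild type library 3 and 483 without wild type library 4, and 356 without ob/ob libraries 1 and 3 together, a fit in which the lone ob/ob library was assumed to vary like the wild type ones. With the hepatocyte score as a covariate limma called 0 genes, with 598 below an unadjusted p of 0.05. At 9 weeks genotype accounted for 93.3% of the variance of that score. Besides Cd209f, of the genes called and named here the changes of Selenop and Hamp turned with it, to 0.17 ± 0.51 (adjusted p = 0.969) and -0.47 ± 1.26 (adjusted p = 0.968). So did that of Dab2, described under the other observations, to 0.73 ± 0.57 (adjusted p = 0.910). Hamp is itself on the hepatocyte list, so the score contains its level and its turn decides nothing. Genotype and sequencing lane cannot be told apart, since each group was run on its own lane.

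The largest rise at 9 weeks was in Apoa4, a lipoprotein gene of intestine and fatty liver, from 0.240 ± 0.0461 to 101 ± 21.8 FPKM (SD, n = 4 and 3), a log2 change of 6.34 ± 0.14 (adjusted p = 1.7e-06). Next by size, besides Gpnmb and Mmp12, were the microsomal fatty acid hydroxylase Cyp4a14 (4.15 ± 0.27), the plasma protein genes Apoa2 (4.04 ± 0.31), Apoc3 (3.72 ± 0.34) and Ttr (3.71 ± 0.24), and H2-Q10 (3.79 ± 0.21), a class I gene whose reads can be shared with its paralogs. The largest fall was in Serpina1e, which fell by 4.42 ± 0.15 (adjusted p = 2.8e-05) and whose near-identical paralogs make its level uncertain. A locus of a small nucleolar RNA and a gene with a clone-based name, kept because the rule left out a locus only where each of its names matched, fell by 2.84 ± 0.31, Car11 fell by 2.01 ± 0.37, and the prostacyclin synthase gene Ptgis fell by 2.01 ± 0.25. Cntfr, which encodes a subunit of a cytokine receptor, fell by 1.57 ± 0.30, and the major urinary protein gene Mup20, a member of a family of near-identical copies, fell by 1.46 ± 0.25. In the GENCODE M21 annotation of GRCm38, the build named mm10 in the submitters' processing notes, the gene bodies lie with Gpnmb at 49036546 to 49070929 on chromosome 6, Mmp12 at 7344381 to 7369499 on chromosome 9, Apoa4 at 46240696 to 46243459 on chromosome 9, Cyp4a14 at 115486200 to 115496142 on chromosome 4, Serpina1e at 103946931 to 103958975 on chromosome 12, Cd209f at 4102787 to 4105835 on chromosome 8, Cxcl13 at 95956951 to 95961068 on chromosome 5 and Folr2 at 101839988 to 101857194 on chromosome 7.

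11 of 20 lipid-associated macrophage genes rose, none fell and 9 did not pass the test, and 11 rose and 0 fell when adjusted over the list alone (camera adjusted p = 5.0e-08, higher, and adjusted p = 0.0444 with an estimated correlation). Cd63, a tetraspanin of late endosomes, rose by 2.36 ± 0.31 and the integrin gene Itgax by 1.80 ± 0.27. This was the list whose call held with an estimated correlation at 9 weeks. 10 of 20 genes of monocytes and recruited macrophages rose, 1 fell and 9 did not pass the test (12 rose and 1 fell when adjusted over the list alone; camera adjusted p = 5.6e-07, higher, and adjusted p = 0.234 with an estimated correlation). Chil3, a chitinase-like secreted protein, rose by 3.26 ± 0.68. Among 24 Kupffer cell identity genes, 1 fell, none rose and 23 did not pass the test, and 0 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.0748, lower). The fallen gene was Folr2. Clec4f, the Kupffer cell lectin, stood at -0.39 ± 0.16 (adjusted p = 0.163) and Timd4, the phosphatidylserine receptor of long-lived resident cells, at -0.38 ± 0.18 (adjusted p = 0.225), neither past the threshold. Camera did call the list, with an adjusted p of 3.0e-04 without ob/ob library 3, 0.00940 without wild type library 2, 0.0424 without wild type library 3 and 7.0e-04 without ob/ob libraries 1 and 3 together. 3 of 17 alternative activation genes rose, 3 fell and 11 did not pass the test. Adjusted over the list alone, 4 rose and 5 fell (camera adjusted p = 0.473, higher). Arg1, an arginase that hepatocytes also express, rose by 1.55 ± 0.14 and the fungal glucan receptor Clec7a by 0.87 ± 0.17, and the chemokine gene Ccl24 fell by 0.68 ± 0.16. None of 14 dendritic cell genes passed the test over all genes or when adjusted over the list alone (camera adjusted p = 0.855, lower). The smallest p among them was that of Bst2 (log2 change -0.50 ± 0.13, adjusted p = 0.0549). The median log2 change of the list was 0.020 and its mean -0.15, while camera placed it lower.

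26 of 32 hepatocyte genes rose, 1 fell and 5 did not pass the test (29 rose and 2 fell when adjusted over the list alone; camera adjusted p = 1.9e-27, higher, and adjusted p = 0.234 with an estimated correlation). Cyp3a11, a drug-metabolizing cytochrome, rose by 3.55 ± 0.28. The gene that fell was Mup20. Among 13 neutrophil genes, 7 rose, none fell and 6 did not pass the test, and 7 rose and 0 fell when adjusted over the list alone (camera adjusted p = 2.2e-06, higher, and adjusted p = 0.350 with an estimated correlation). Wfdc21 (2.50 ± 0.35) and Retnlg (2.46 ± 0.20) and the calprotectin genes S100a8 (2.16 ± 0.52) and S100a9 (2.15 ± 0.50) were its largest rises. 5 of 7 erythroid genes rose, none fell and 2 did not pass the test. With adjustment over the list alone, 5 rose and 0 fell (camera adjusted p = 8.8e-04, higher, and adjusted p = 0.350 with an estimated correlation). The globin genes Hbb-bs (2.55 ± 0.42) and Hba-a1 (2.47 ± 0.38) rose, with reads that can be shared between near-identical copies. 5 of 15 B and plasma cell genes rose, none fell and 10 did not pass the test, and 10 rose and 1 fell when adjusted over the list alone (camera adjusted p = 2.3e-05, higher, and adjusted p = 0.318 with an estimated correlation). The immunoglobulin genes Ighd (1.35 ± 0.21) and Igkc (1.24 ± 0.25) rose, as members of a family with shared sequence. None of 12 T and NK cell genes passed the test over all genes or when adjusted over the list alone (camera adjusted p = 0.00108, higher, and adjusted p = 0.458 with an estimated correlation). Without ob/ob library 3, 7 of them rose. Among 20 sinusoidal endothelial genes, 3 fell, none rose and 17 did not pass the test, and 0 rose and 17 fell when adjusted over the list alone (camera adjusted p = 1.0e-06, lower, and adjusted p = 0.458 with an estimated correlation). Bmp2, an endothelial signal for iron regulation, fell by 1.26 ± 0.30 and the hyaluronan scavenger receptor gene Stab2 fell by 0.74 ± 0.17. None of 9 hepatic stellate cell genes passed the test. Of the same list, 0 rose and 4 fell when adjusted over the list alone (camera adjusted p = 0.202, lower). The call appeared, with an adjusted p of 0.0336 without ob/ob libraries 1 and 3 together. 1 of 5 platelet genes rose, none fell and 4 did not pass the test, and 2 rose and 0 fell when adjusted over the list alone (camera adjusted p = 0.0956, higher). The gene that rose was Selp, the adhesion molecule of platelets and endothelium (2.62 ± 0.33). No cholangiocyte gene had a mean of at least 1 FPKM at 9 weeks.

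5 of 37 NRF2 target genes rose, 1 fell and 31 did not pass the test (6 rose and 5 fell when adjusted over the list alone; camera adjusted p = 0.0340, higher, and adjusted p = 0.478 with an estimated correlation). The rises were led by glutathione transferases, Mgst1 (2.24 ± 0.20), Gstm3 (2.05 ± 0.22) and Gsta3 (1.89 ± 0.19), and the malic enzyme gene Me1 (1.81 ± 0.22). Mgst1 was also on the monocyte list. In ob/ob libraries 1, 3 and 4 it stood at 421, 348 and 222 FPKM, with Alb at 3500, 3174 and 2295. Gstm3 and Me1 had wild type means of only 0.063 and 0.23 FPKM. With the hepatocyte score in a joint fit Gsta3 turned to -0.51 (limma adjusted p = 0.932). Which cells these transcripts came from was not tested. The list lost its call, with an adjusted p of 0.0507 under median-ratio scaling and 0.0712 without ob/ob library 1, 0.190 without ob/ob library 3, 0.0601 without wild type library 4 and 0.961 without ob/ob libraries 1 and 3 together. In the same libraries the hepatocyte score was higher by 2.08 in ob/ob. The best known NRF2 targets and regulators did not pass the test over all genes, with log2 changes of Nfe2l2 (-0.0037 ± 0.10), Keap1 (-0.29 ± 0.082), Gclc (0.089 ± 0.070), Gclm (-0.014 ± 0.091), Nqo1 (0.42 ± 0.20), Hmox1 (-0.48 ± 0.12) and Txnrd1 (0.28 ± 0.14), and Nfe2l2 stood at 0.049 and Gclm at 0.038 under median-ratio scaling. Adjusted over their lists alone, Hmox1 and Keap1 were among the members that fell. Srxn1, sulfiredoxin, stood at 0.19 ± 0.15 (adjusted p = 0.434). Among 16 NRF2 regulators, 1 fell, none rose and 15 did not pass the test, and 0 rose and 3 fell when adjusted over the list alone (camera adjusted p = 0.456, lower). The gene that fell was the locus of Mafg and Sirt7, overlapping genes whose reads were not separated (-0.37 ± 0.071). Gata4, a factor of endothelial and stellate cells, stood at -0.87 ± 0.42 (adjusted p = 0.233). 1 of 29 antioxidant enzymes outside the NRF2 list rose, 3 fell and 25 did not pass the test. Adjusted over the list alone, 1 rose and 3 fell (camera adjusted p = 0.812, lower). Gpx3, the secreted glutathione peroxidase, rose by 0.97 ± 0.16, and the selenium carrier gene Selenop fell by 0.73 ± 0.15, Gpx4 fell by 0.36 ± 0.074 and Selenow fell by 0.32 ± 0.074. None of 7 NADPH oxidase subunits passed the test over all genes or when adjusted over the list alone (camera adjusted p = 0.479, higher).

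3 of 21 inflammatory cytokine and mediator genes rose, none fell and 18 did not pass the test (4 rose and 0 fell when adjusted over the list alone; camera adjusted p = 0.00112, higher, and adjusted p = 0.458 with an estimated correlation). These were the acute phase gene Saa3 (2.82 ± 0.41), the prostaglandin synthase gene Ptgs2 (1.53 ± 0.23) and the chemokine gene Ccl4. The classical cytokine genes did not pass, with log2 changes of Tnf (0.14 ± 0.19), Il1b (0.27 ± 0.29) and Ccl2 (0.46 ± 0.19). Igfbp7, an insulin-like growth factor binding protein gene, stood at -1.35 ± 0.35 and the leptin receptor gene Lepr at -0.32 ± 0.22 (adjusted p = 0.0572 and 0.398). Among 30 type I interferon response genes, 2 fell, none rose and 28 did not pass the test, and 0 rose and 8 fell when adjusted over the list alone (camera adjusted p = 6.8e-04, lower, and adjusted p = 0.643 with an estimated correlation). The genes that fell were Ifi27l2a (-0.87 ± 0.21) and Oas2 (-0.72 ± 0.17). The call was lost, with an adjusted p of 0.0582 without ob/ob library 1 and 0.735 without ob/ob libraries 1 and 3 together (placed higher). None of 15 MHC class II presentation genes passed the test over all genes or when adjusted over the list alone (camera adjusted p = 0.149, higher). Camera did call the list, with an adjusted p of 4.7e-04 without wild type library 3.

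8 of 14 fatty acid synthesis genes rose, none fell and 6 did not pass the test, and 9 rose and 0 fell when adjusted over the list alone (camera adjusted p = 5.8e-08, higher, and adjusted p = 0.234 with an estimated correlation). Scd1, the stearoyl-CoA desaturase, rose by 3.70 ± 0.22, the elongase Elovl6 by 1.56 ± 0.23 and the desaturase Fads2 by 1.61 ± 0.20. 7 of 19 lipid uptake and storage genes rose, none fell and 12 did not pass the test (8 rose and 1 fell when adjusted over the list alone; camera adjusted p = 1.5e-04, higher, and adjusted p = 0.108 with an estimated correlation). Dgat2, which makes triglyceride, rose by 2.05 ± 0.24 and the lipid droplet gene Hilpda by 1.01 ± 0.16. Among 22 cholesterol biosynthesis genes, 3 rose, none fell and 19 did not pass the test, and 3 rose and 0 fell when adjusted over the list alone (camera adjusted p = 0.00182, higher, and adjusted p = 0.458 with an estimated correlation). This call ended, with an adjusted p of 0.134 without ob/ob libraries 1 and 3 together. 2 of 12 LXR target genes rose, none fell and 10 did not pass the test. Of the same list, 3 rose and 0 fell when adjusted over the list alone (camera adjusted p = 0.0514, higher). These were Scd2 (0.94 ± 0.17) and the unseparated locus of Apoc2 and Apoc4 (2.33 ± 0.18). Camera did call the list, with an adjusted p of 0.0154 without ob/ob library 4 and 0.0192 without wild type library 1. 3 of 22 fatty acid oxidation genes rose, none fell and 19 did not pass the test, and 3 rose and 0 fell when adjusted over the list alone (camera adjusted p = 0.00190, higher, and adjusted p = 0.408 with an estimated correlation). The call was lost, with an adjusted p of 0.267 without ob/ob libraries 1 and 3 together. 3 of 19 glycolysis genes rose, none fell and 16 did not pass the test (4 rose and 1 fell when adjusted over the list alone; camera adjusted p = 0.00396, higher, and adjusted p = 0.458 with an estimated correlation). Pyruvate kinase, Pkm, rose by 0.58 ± 0.11. Camera no longer called the list, with an adjusted p of 0.126 without ob/ob libraries 1 and 3 together. None of 40 nuclear oxidative phosphorylation genes passed the test over all genes or when adjusted over the list alone (camera adjusted p = 0.498, lower). The call appeared, with an adjusted p of 0.0365 without ob/ob libraries 1 and 3 together. Hepatocyte transcripts moved with these lists, with Alb at 2295 FPKM or more in each ob/ob library and 378 or less in each wild type library.

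17 of 28 proliferation genes rose, none fell and 11 did not pass the test. Adjusted over the list alone, 22 rose and 0 fell (camera adjusted p = 1.4e-15, higher, and adjusted p = 0.318 with an estimated correlation). The ribonucleotide reductase gene Rrm2 rose by 1.48 ± 0.20 and the cyclin gene Ccnb1 by 1.35 ± 0.21. 2 of 35 lysosome genes rose, none fell and 33 did not pass the test, and 2 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.456, higher). Atp6v0d2, a macrophage subunit of the lysosomal proton pump, rose by 2.06 ± 0.27. 2 of 19 iron handling genes rose, none fell and 17 did not pass the test (2 rose and 1 fell when adjusted over the list alone; camera adjusted p = 0.847, higher). These were the hepatocyte genes for hepcidin, Hamp (2.17 ± 0.40), and ceruloplasmin, Cp (1.98 ± 0.16). The median log2 change of the list was -0.087 and its mean 0.10, while camera placed it higher. Among 23 unfolded protein response genes, 1 fell, none rose and 22 did not pass the test, and 0 rose and 0 fell when adjusted over the list alone (camera adjusted p = 0.206, lower). The gene that fell was Dnajb9 (-0.41 ± 0.10). 1 of 25 immediate early and heat shock genes, which report stress during cell isolation, rose, 2 fell and 22 did not pass the test. With adjustment over the list alone, 1 rose and 2 fell (camera adjusted p = 0.847, lower). Egr2, a transcription factor, rose by 1.07 ± 0.17, and the chaperone genes Hspa1a and Dnajb1 fell by 0.65 ± 0.13 and 0.59 ± 0.089. Of 2 mitochondrially encoded loci tested, 2 rose, mt-Cytb (1.32 ± 0.23) and the unseparated mt-Nd1 and mt-Nd2 (1.23 ± 0.24). Of 4 sex-linked genes tested, limma called 0 at either age, with 0 at 9 weeks and 1 at 14 weeks below an unadjusted p of 0.05.

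Fry, which asks whether the genes of a list move on balance 1 way and does not compare them with other genes, called 11 of 32 lists at 9 weeks, and camera called 17. Both called 10 in the same direction. By fry alone 1 was called, platelet and megakaryocyte (0.0255 by fry and 0.0956 by camera), and by camera alone 7, the NRF2 target list among them (adjusted p = 0.117 by fry).

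**Figure D1:**
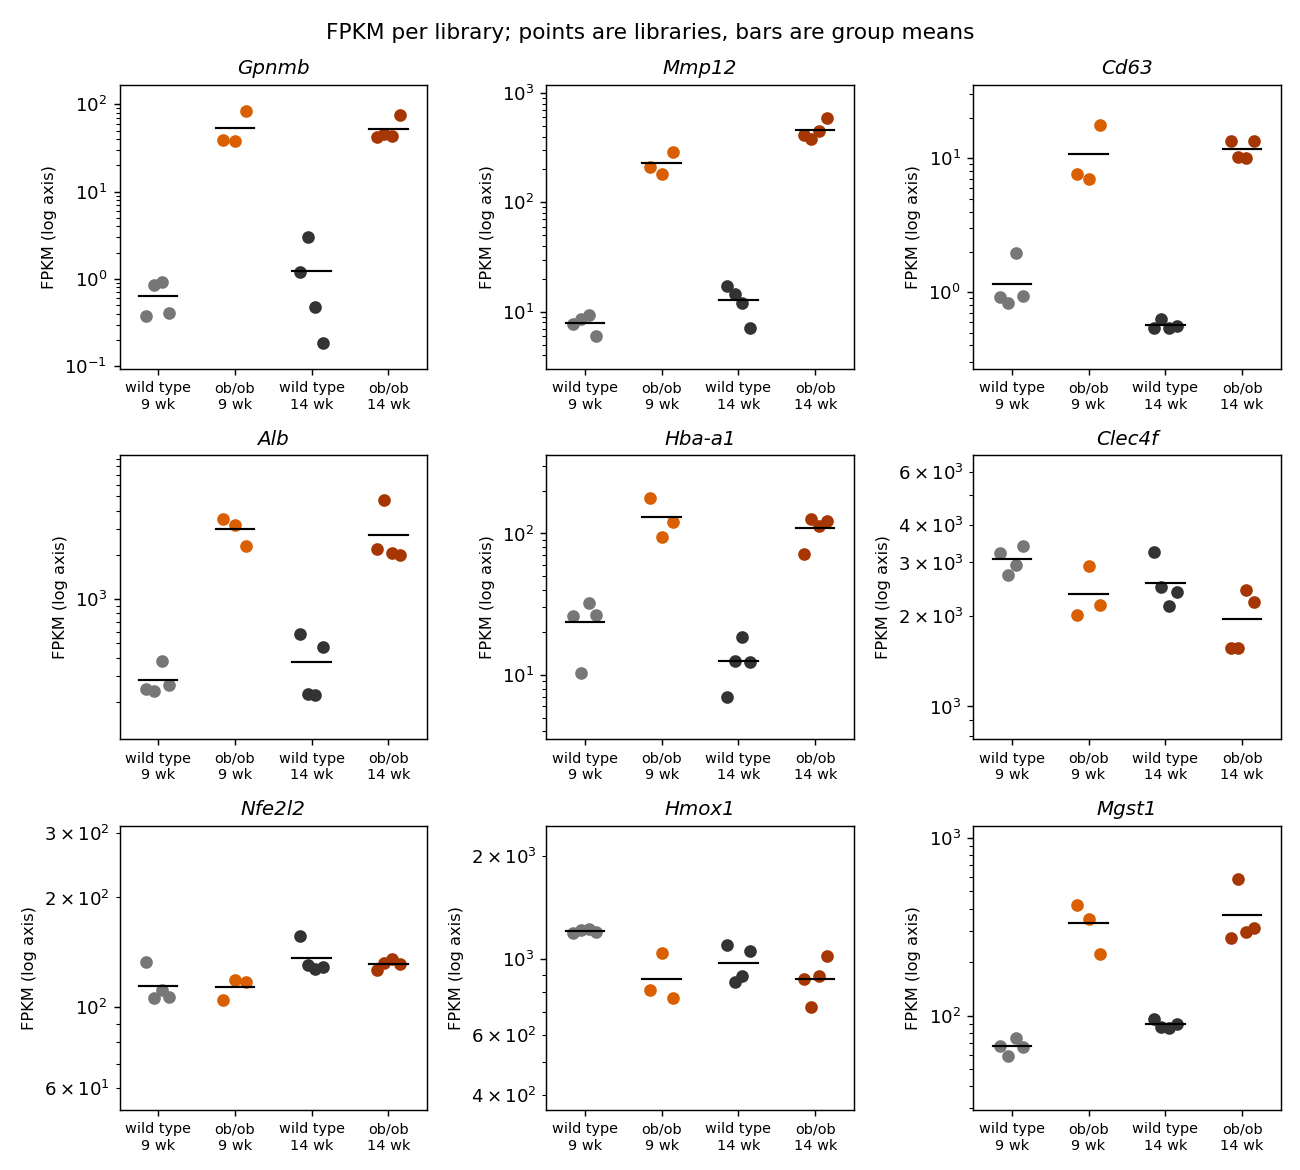
FPKM of 9 genes on log axes, with a point per library and a bar at each group mean, for wild type and ob/ob libraries at 9 and 14 weeks. Gpnmb lay between 37.9 and 83.5 FPKM in ob/ob and between 0.379 and 0.931 in wild type libraries at 9 weeks, while those of Nfe2l2 overlapped, at 105 to 119 and 106 to 133 FPKM.

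The same question was asked at 14 weeks. Mmp12 and Gpnmb were again the macrophage genes with the largest rises, Mmp12 from 12.8 ± 4.31 to 459.6 ± 92.5 FPKM (SD, n = 4 each), a log2 change of 5.10 ± 0.25 (SE), and Gpnmb by 4.69 ± 0.37. Cd63 rose by 3.02 ± 0.11, Itgax by 2.02 ± 0.27 and the proton pump gene Atp6v0d2 by 2.71 ± 0.16. T cell receptor genes rose, Trbc1 by 1.56 ± 0.34 and Trbc2 by 1.51 ± 0.40, as did the cell cycle genes Ube2c (1.51 ± 0.18) and Ccna2 (1.49 ± 0.11). Cd163, the haemoglobin scavenger receptor of Kupffer cells, fell by 0.89 ± 0.20, Cd209f fell by 2.52 ± 0.22 and Cxcl13 fell by 2.42 ± 0.33. Nfe2l2 was at 131 ± 3.80 FPKM (SD, n = 4) against 136 ± 14.1 FPKM (SD, n = 4) and did not pass (adjusted p = 0.735).

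Of 11612 genes tested with limma, 1548 passed, 763 higher and 785 lower in ob/ob (49.3% higher). Median-ratio scaling gave 920 higher and 368 lower of 1288 (71.4% higher). Changes of at least 2-fold were counted in 394 genes that rose and 31 that fell. The count was 978 without ob/ob library 2, 945 without ob/ob library 4, 956 without wild type library 2 and 942 without wild type library 4, and 1356 without ob/ob library 2 and wild type library 1 together, which had the highest hepatocyte score and the lowest wild type endothelial score. With the hepatocyte score as a covariate limma called 9 genes, Cd63, Mmp12 and Atp6v0d2 among them, with 1228 below an unadjusted p of 0.05. Of the genes called and named at 14 weeks, the change of Hamp turned with it, to -0.18 ± 0.41 (adjusted p = 0.917). That turn decides nothing, since Hamp is a member of the list that gives the score.

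The largest rise was again in Apoa4 (5.79 ± 0.36, adjusted p = 2.3e-04). Mmp12 and Gpnmb came next by size, and then liver genes, with Cyp4a14 (4.03 ± 0.29) and Cyp3a11 (3.48 ± 0.47), the lipoprotein gene Apob (3.31 ± 0.37), H2-Q10 (3.25 ± 0.37), whose reads can be shared with its paralogs, and the lipid droplet gene Hsd17b13 (3.24 ± 0.33). Serpina1e fell by 4.12 ± 0.39, with the same uncertainty from its paralogs. Prmt2, an arginine methyltransferase gene, fell by 3.40 ± 0.89, with a wild type mean of 98.2 ± 84.2 FPKM (SD, n = 4). Ptgis fell by 2.19 ± 0.23, the secreted protease gene Htra1 fell by 1.88 ± 0.33, Tox2 fell by 1.58 ± 0.19, and the leukotriene synthase gene Ltc4s fell by 1.57 ± 0.26. On GRCm38 the gene bodies lie with Cd63 at 128900989 to 128912822 on chromosome 10, Atp6v0d2 at 19876841 to 19922605 on chromosome 4, Prmt2 at 76207222 to 76237865 on chromosome 10, Ltc4s at 50236461 to 50238616 on chromosome 11, Nfe2l2 at 75675513 to 75704641 on chromosome 2 and Srxn1 at 152105516 to 152111376 on chromosome 2.

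10 of 20 lipid-associated macrophage genes rose, none fell and 10 did not pass the test, and 12 rose and 0 fell when adjusted over the list alone (camera adjusted p = 8.7e-10, higher, and adjusted p = 0.151 with an estimated correlation). 10 of 18 genes of monocytes and recruited macrophages rose, 1 fell and 7 did not pass the test (10 rose and 2 fell when adjusted over the list alone; camera adjusted p = 3.2e-06, higher, and adjusted p = 0.151 with an estimated correlation). Chil3 rose by 2.87 ± 0.45, Ccr2 by 1.81 ± 0.23 and the unseparated locus of S100a3 and S100a4 by 1.94 ± 0.27. Among 24 Kupffer cell identity genes, 1 fell, none rose and 23 did not pass the test, and 0 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.0838, lower). The gene that fell was Cd163. Clec4f stood at -0.41 ± 0.20 (adjusted p = 0.192) and Timd4 at -0.38 ± 0.19 (adjusted p = 0.222). Camera did call the list, with an adjusted p of 0.0297 under median-ratio scaling and 0.0287 without ob/ob library 3, 0.0213 without ob/ob library 4 and 0.0125 without wild type library 3. 4 of 16 alternative activation genes rose, 5 fell and 7 did not pass the test. Of the same list, 5 rose and 5 fell when adjusted over the list alone (camera adjusted p = 0.837, higher). Retnla, a resistin-like protein gene induced by interleukin signals, fell by 1.77 ± 0.46, while Arg1 rose by 1.32 ± 0.34 and Clec7a by 1.11 ± 0.18. The median log2 change of the list was -0.19 and its mean 0.081, while camera placed it higher. 3 of 14 dendritic cell genes rose, 1 fell and 10 did not pass the test, and 5 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.114, higher). The migration receptor gene Ccr7 rose by 1.43 ± 0.19 and the chemokine gene Ccl22 rose too, while Bst2 fell by 0.55 ± 0.093. The median log2 change of the list was -0.071 and its mean 0.11, while camera placed it higher.

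21 of 33 hepatocyte genes rose, none fell and 12 did not pass the test (25 rose and 0 fell when adjusted over the list alone; camera adjusted p = 9.4e-19, higher, and adjusted p = 0.264 with an estimated correlation). Haemopexin, Hpx, rose by 3.14 ± 0.38. Among 13 T and NK cell genes, 8 rose, none fell and 5 did not pass the test, and 12 rose and 1 fell when adjusted over the list alone (camera adjusted p = 1.7e-09, higher, and adjusted p = 0.151 with an estimated correlation). The interleukin receptor gene Il2rb rose by 1.76 ± 0.30, and the unseparated locus of Klrb1b and Klrb1c by 1.64 ± 0.19. 8 of 16 B and plasma cell genes rose, none fell and 8 did not pass the test. Adjusted over the list alone, 12 rose and 1 fell (camera adjusted p = 2.3e-08, higher, and adjusted p = 0.254 with an estimated correlation). Fcmr, the receptor for IgM, rose by 1.13 ± 0.21. 6 of 12 neutrophil genes rose, none fell and 6 did not pass the test, and 8 rose and 1 fell when adjusted over the list alone (camera adjusted p = 2.6e-05, higher, and adjusted p = 0.254 with an estimated correlation). Lcn2, the iron-sequestering lipocalin, rose by 1.78 ± 0.36, and S100a8 by 1.21 ± 0.33. 5 of 7 erythroid genes rose, none fell and 2 did not pass the test (5 rose and 0 fell when adjusted over the list alone; camera adjusted p = 7.5e-06, higher, and adjusted p = 0.254 with an estimated correlation). Hba-a1 rose by 3.05 ± 0.28, again with reads shared between copies. Among 5 platelet genes, 1 rose, none fell and 4 did not pass the test, and 1 rose and 0 fell when adjusted over the list alone (camera adjusted p = 0.0216, higher, and adjusted p = 0.254 with an estimated correlation). This was Selp (2.64 ± 0.26). 1 of 20 sinusoidal endothelial genes fell, none rose and 19 did not pass the test. With adjustment over the list alone, 0 rose and 1 fell (camera adjusted p = 0.0194, lower, and adjusted p = 0.664 with an estimated correlation). This was Cdh5, the endothelial cadherin (-0.41 ± 0.077). Without ob/ob library 2 and wild type library 1, 6 fell. The call was lost, with an adjusted p of 0.0999 without ob/ob library 4 and 0.112 without wild type library 3. 3 of 12 hepatic stellate cell genes rose, none fell and 9 did not pass the test, and 3 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.0296, higher, and adjusted p = 0.522 with an estimated correlation). They were the collagen genes Col3a1 (2.50 ± 0.65) and Col1a2 (0.68 ± 0.18) and the protease inhibitor gene Timp1 (1.12 ± 0.17). Without the same pair of libraries, 1 rose and 1 fell. Camera no longer called the list, with an adjusted p of 0.110 under median-ratio scaling and 0.312 without ob/ob library 2, 0.05003 without ob/ob library 3, 0.363 without wild type library 1 and 0.415 without ob/ob library 2 and wild type library 1 together (placed lower). The cholangiocyte list had 1 gene tested, Krt18, at 0.66 ± 0.32 (adjusted p = 0.198).

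4 of 36 NRF2 target genes rose, 4 fell and 28 did not pass the test (7 rose and 4 fell when adjusted over the list alone; camera adjusted p = 0.0292, higher, and adjusted p = 0.478 with an estimated correlation). Mgst1 (1.95 ± 0.22) and Gstm3 (1.72 ± 0.42) led the rises, the oxidative stress gene Osgin1 fell by 0.68 ± 0.086, and Gstp1, a glutathione transferase, fell by 0.52 ± 0.11. This call ended, with an adjusted p of 0.05003 without ob/ob library 3. Srxn1 rose by 0.50 ± 0.13 (adjusted p = 0.0420). The other NRF2 genes named in advance did not pass, with log2 changes of Nfe2l2 (-0.046 ± 0.083), Keap1 (-0.14 ± 0.063), Gclc (0.072 ± 0.11), Gclm (-0.041 ± 0.12), Nqo1 (0.24 ± 0.21), Hmox1 (-0.16 ± 0.13) and Txnrd1 (0.24 ± 0.16), and Nfe2l2 stood at 0.039 and Gclm at 0.043 under median-ratio scaling. The hepatocyte score was higher by 1.73 in the ob/ob libraries. Among 16 NRF2 regulators, 1 fell, none rose and 15 did not pass the test, and 0 rose and 0 fell when adjusted over the list alone (camera adjusted p = 0.364, lower). This was again the locus of Mafg and Sirt7 (-0.35 ± 0.10). Gata4 stood at -0.53 ± 0.36 (adjusted p = 0.352). 1 of 29 antioxidant enzymes outside the NRF2 list fell, none rose and 28 did not pass the test. Of the same list, 0 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.104, higher). This was the methionine sulfoxide reductase gene Msrb2 (-0.60 ± 0.11). None of 7 NADPH oxidase subunits passed the test over all genes or when adjusted over the list alone (camera adjusted p = 0.857, lower).

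3 of 21 inflammatory cytokine and mediator genes rose, 1 fell and 17 did not pass the test (6 rose and 2 fell when adjusted over the list alone; camera adjusted p = 0.0194, higher, and adjusted p = 0.478 with an estimated correlation). Ccl5 rose by 1.23 ± 0.16, Ptgs2 by 1.02 ± 0.21 and Cxcl1 by 0.99 ± 0.11, and Il6 fell by 0.82 ± 0.12. Tnf (-0.26 ± 0.14), Il1b (-0.30 ± 0.18) and Ccl2 (0.32 ± 0.10) did not pass, nor did Igfbp7 (-0.81 ± 0.41) and Lepr (0.11 ± 0.14). The list lost its call, with an adjusted p of 0.0647 without ob/ob library 2. Among 30 type I interferon response genes, 3 fell, none rose and 27 did not pass the test, and 0 rose and 5 fell when adjusted over the list alone (camera adjusted p = 0.0591, lower). Oas2 fell by 0.62 ± 0.13 and the signal transducer gene Stat2 fell by 0.32 ± 0.075. The call appeared, with an adjusted p of 0.0255 without ob/ob library 1, 0.0484 without wild type library 1, 0.0407 without wild type library 2 and 0.0472 without wild type library 4. 1 of 15 MHC class II presentation genes rose, none fell and 14 did not pass the test. Adjusted over the list alone, 0 rose and 0 fell (camera adjusted p = 0.0296, higher, and adjusted p = 0.582 with an estimated correlation). This was H2-DMb2 (0.43 ± 0.11). Camera no longer called the list, with an adjusted p of 0.0517 under median-ratio scaling and 0.0633 without ob/ob library 3, 0.0745 without ob/ob library 4, 0.171 without wild type library 3 and 0.0585 without wild type library 4.

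6 of 15 fatty acid synthesis genes rose, none fell and 9 did not pass the test, and 10 rose and 0 fell when adjusted over the list alone (camera adjusted p = 8.1e-07, higher, and adjusted p = 0.266 with an estimated correlation). Scd1 rose by 2.72 ± 0.44 and Elovl6 by 1.02 ± 0.23. 7 of 19 lipid uptake and storage genes rose, none fell and 12 did not pass the test (9 rose and 0 fell when adjusted over the list alone; camera adjusted p = 2.2e-06, higher, and adjusted p = 0.151 with an estimated correlation). The fatty acid carriers Fabp4 and Cd36 rose by 1.54 ± 0.31 and 1.25 ± 0.22, and Dgat2 by 1.83 ± 0.28. Among 21 cholesterol biosynthesis genes, 2 rose, none fell and 19 did not pass the test, and 1 rose and 0 fell when adjusted over the list alone (camera adjusted p = 0.0223, higher, and adjusted p = 0.478 with an estimated correlation). This call ended, with an adjusted p of 0.0650 without ob/ob library 2, 0.0805 without wild type library 3 and 0.0626 without ob/ob library 2 and wild type library 1 together. 2 of 12 LXR target genes rose, none fell and 10 did not pass the test. With adjustment over the list alone, 2 rose and 0 fell (camera adjusted p = 0.0223, higher, and adjusted p = 0.508 with an estimated correlation). The list lost its call, with an adjusted p of 0.0506 without ob/ob library 4 and 0.0691 without wild type library 3. 1 of 22 fatty acid oxidation genes rose, none fell and 21 did not pass the test, and 1 rose and 0 fell when adjusted over the list alone (camera adjusted p = 1.1e-05, higher, and adjusted p = 0.328 with an estimated correlation). This was Hadha, of the mitochondrial trifunctional protein (0.37 ± 0.062). 5 of 18 glycolysis genes rose, none fell and 13 did not pass the test (6 rose and 1 fell when adjusted over the list alone; camera adjusted p = 0.00264, higher, and adjusted p = 0.478 with an estimated correlation). The lactate exporter gene Slc16a3 rose by 1.05 ± 0.19 and Ldha by 0.60 ± 0.12. Among 40 nuclear oxidative phosphorylation genes, 1 rose, 5 fell and 34 did not pass the test, and 1 rose and 5 fell when adjusted over the list alone (camera adjusted p = 0.937, lower). Uqcrfs1 rose by 0.30 ± 0.056, and Cox7c fell by 0.37 ± 0.081. Alb was at 1989.6 FPKM or more in each ob/ob library and at 581 or less in each wild type library of this age.

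20 of 29 proliferation genes rose, none fell and 9 did not pass the test. Of the same list, 23 rose and 0 fell when adjusted over the list alone (camera adjusted p = 1.3e-23, higher, and adjusted p = 0.151 with an estimated correlation). Birc5, of the chromosomal passenger complex, rose by 1.46 ± 0.17 and the mitotic regulator Cdc20 by 1.43 ± 0.17. 2 of 35 lysosome genes rose, 1 fell and 32 did not pass the test, and 2 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.0223, higher, and adjusted p = 0.664 with an estimated correlation). Besides Atp6v0d2, Naglu rose by 0.36 ± 0.091, and Sgsh fell by 0.56 ± 0.10. The call was lost, with an adjusted p of 0.0666 without ob/ob library 3, 0.0857 without ob/ob library 4, 0.169 without wild type library 3 and 0.0579 without wild type library 4. 2 of 19 iron handling genes rose, 1 fell and 16 did not pass the test (2 rose and 1 fell when adjusted over the list alone; camera adjusted p = 0.538, higher). Hamp rose by 1.53 ± 0.41 and Cp by 1.84 ± 0.25. The median log2 change of the list was -0.022 and its mean 0.061, while camera placed it higher. Among 23 unfolded protein response genes, 6 fell, none rose and 17 did not pass the test, and 0 rose and 10 fell when adjusted over the list alone (camera adjusted p = 0.0194, lower, and adjusted p = 0.363 with an estimated correlation). Dnajb9 fell by 0.55 ± 0.10, the chaperone gene Hsp90b1 fell by 0.43 ± 0.090 and the stress regulator gene Atf4 fell by 0.38 ± 0.078. 4 of 25 immediate early and heat shock genes fell, none rose and 21 did not pass the test. Adjusted over the list alone, 0 rose and 5 fell (camera adjusted p = 0.0679, lower). Fosb fell by 1.01 ± 0.28, Jun fell by 0.68 ± 0.15 and Egr1 fell by 0.64 ± 0.16. Camera did call the list, with an adjusted p of 0.0228 under median-ratio scaling and 0.0397 without ob/ob library 2, 0.0295 without wild type library 3 and 0.0209 without wild type library 4. Of 2 mitochondrially encoded loci tested, 1 rose (mt-Cytb, 0.99 ± 0.27), and 0 did so without ob/ob library 2 and wild type library 1.

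At 14 weeks fry called 14 of 32 lists and camera 22, with 12 called by both in the same direction. Fry alone called 2, both lower in ob/ob, NRF2 regulators (0.0421 by fry and 0.364 by camera) and type I interferon response (0.0156 by fry and 0.0591 by camera). Camera alone called 10, again with the NRF2 target list (adjusted p = 0.470 by fry).

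**Figure D2:**
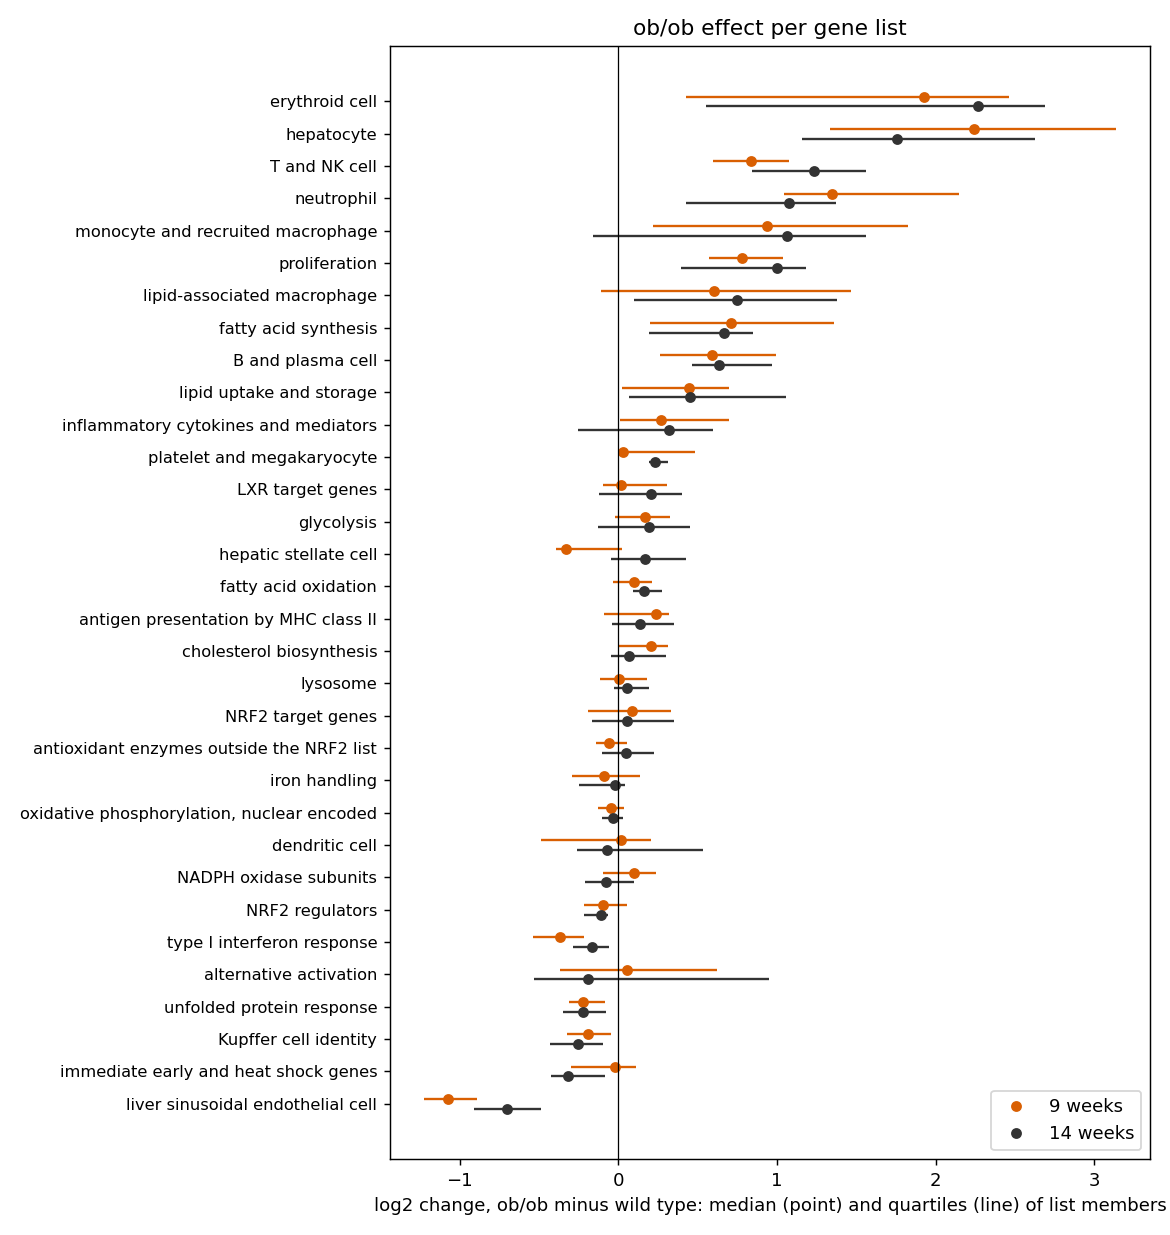
Median log2 change, ob/ob minus wild type, of the tested members of each gene list (points) with their quartiles (lines), at 9 and 14 weeks. The hepatocyte list had a median of 2.24 at 9 weeks and 1.75 at 14 weeks, and the NRF2 target list 0.089 and 0.055.

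The last comparison asked whether the ob/ob effect differed between the ages. Of 11383 genes tested at both ages, 438 rose at both, Gpnmb, Mmp12, Cd63, Ccr2 and Scd1 among them, and 154 fell at both, Cd209f and Cxcl13 among them, with 0 called in opposite directions. Of the genes called at 9 weeks, 99.1% had a change of the same sign at 14 weeks, and of those called at 14 weeks 98.3% had it at 9 weeks, past the threshold at the other age or not. Independent lists of these sizes would share 37.5 and 21.9. The count called in the same direction at both ages was 592, 317 without ob/ob library 1 at 9 weeks, 379 without ob/ob library 4 at 9 weeks, 361 without wild type library 3 at 9 weeks and 367 without wild type library 4 at 9 weeks, 312 without ob/ob libraries 1 and 3 at 9 weeks together, and 333 with a filter of a mean of 5 FPKM. Across genes, which are not independent replicates, the log2 changes at both ages had a Pearson r of 0.861, a Spearman rho of 0.702, a covariance of 0.202 and a slope of 0.788 for 14 on 9 weeks. The ages share no libraries. At both ages, though, the hepatocyte score was higher in ob/ob (by 2.08 and 1.73) and each group had its own lane. How much of the agreement came from these was not tested.

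**Figure D3:**
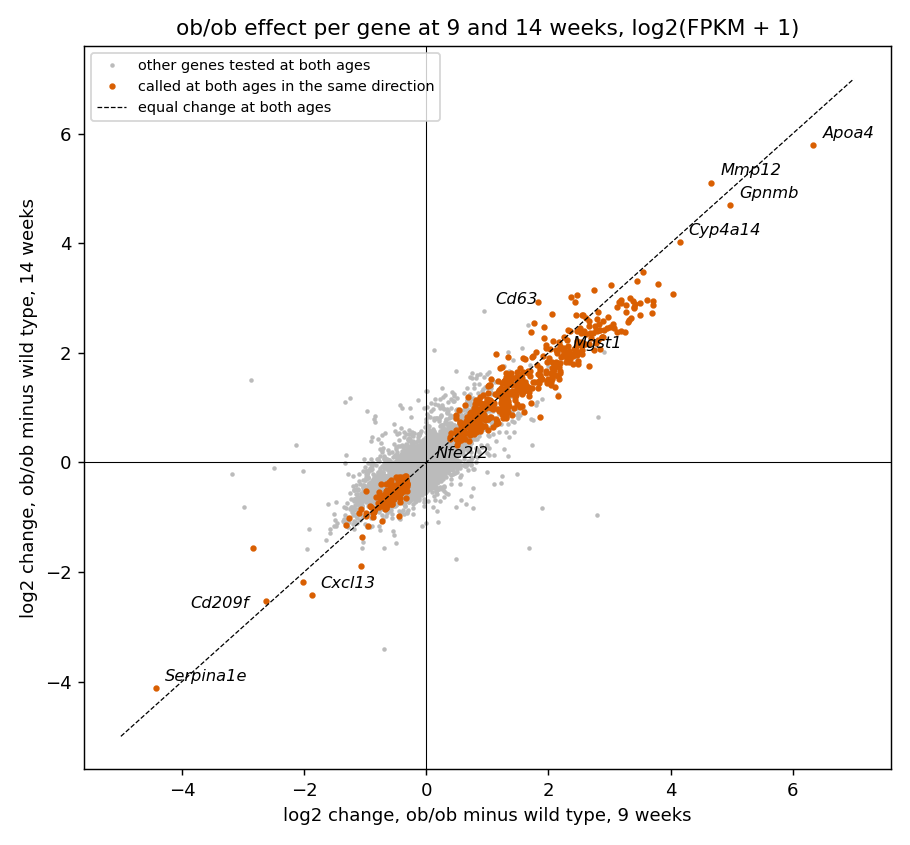
Log2 change of each gene, ob/ob minus wild type on log2(FPKM + 1), at 9 weeks (horizontal) and 14 weeks (vertical), with the genes called at both ages in the same direction in colour and a dashed line of equal change. Across 11383 genes the Pearson r was 0.861, and 0 genes were called in opposite directions.

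No gene's ob/ob effect differed between the ages by limma: 0 of 11568 passed, 492 were below an unadjusted p of 0.05 where 578 would be by chance, and the smallest adjusted p was 0.999. The median 95% half-width of the difference was 0.36 on the log2 scale. Without ob/ob library 4 at 9 weeks 3 passed, Prps2 (-1.03 ± 0.10), Msl3 (-1.03 ± 0.13) and Hccs (-1.05 ± 0.15), neighbouring X chromosome genes higher in ob/ob libraries 1 and 3 at 9 weeks. Without those libraries, 1 passed, Fbxw7 (-4.17 ± 0.16), with the lone ob/ob library at 9 weeks assumed to vary like the other groups. These genes were named after their values were seen.

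As lists, tested with camera on the difference after the values were seen, 10 had an ob/ob effect placed higher at 14 than at 9 weeks, relative to all genes. By adjusted p they were the lists of antioxidant enzymes outside the NRF2 list (0.0262), type I interferon response (4.6e-05), lipid uptake and storage (0.0262), fatty acid oxidation (0.0395), lysosome (0.00586), lipid-associated macrophage (0.0298), dendritic cell (0.0262), T and NK cell (0.00294), liver sinusoidal endothelial cell (0.00283) and hepatic stellate cell (0.00294). An effect placed lower was found for 3, the lists of immediate early and heat shock genes (0.0156), neutrophil (0.0362) and hepatocyte (0.0316). A higher effect can be a smaller fall, as for sinusoidal endothelial genes (median log2 change -1.08 at 9 and -0.70 at 14 weeks). A lower effect can be a smaller rise, as for hepatocyte genes (2.24 and 1.75). With an estimated correlation none of the 13 passed, at adjusted p = 0.846 to 0.906 with an estimated correlation, and fry called 0 of 32 lists. The NRF2 target list was not among them (adjusted p = 0.593). Over all genes no member of a list passed. Adjusted over its list alone 1 did, Retnla of the alternative activation list, named after its value was seen, at -2.26 ± 0.60 (adjusted p = 0.0381 over the list and 0.999 over all genes). It passed in 4 of 15 fits that left out 1 library, and in the other 11 the adjusted p over the list was 0.0639 to 0.121. Without 1 library the difference stayed between -2.04 and -2.76, and without ob/ob libraries 1 and 3 at 9 weeks together it was -2.09. With replicate number as a block the adjusted p over the list was 0.208, though the numbers are not known to pair libraries. Levels at 14 and 9 weeks within a genotype were not compared, because the tables may have been normalized separately.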

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

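Of the tests in this part, the comparison of the lipid-associated macrophage score with the Kupffer cell score, the medians of the NRF2 target list under median-ratio scaling and the camera test of lists on the difference between ages were chosen after the result was seen. So were the hepatocyte score in a joint fit and the genes named from it. Some libraries lay far from the other 3 of their group, by a gap to the nearest library, as a share of the group's range, above Dixon's 95% critical value. This held for 33 of 432 groups of 4 values of a gene and for 7 of 105 of a list score, where chance gives about 1 in 20, here 21.6 and 5.25. In ob/ob library 2 at 14 weeks the shares were those of Apoa2 (0.898), Mgst1 (0.836), Cp (0.842), mt-Cytb (0.950), the locus of mt-Nd1 and mt-Nd2 (0.929), Apob (0.845), Slc16a3 (0.840), Ccr7 (0.974), Hpx (0.884), the cholesterol biosynthesis score (0.904), the mitochondrially encoded score (0.940) and the hepatocyte score (0.911), and its hepatocyte score was 6.23 against 4.75 to 4.88 in the others. In wild type library 1 at 14 weeks they were those of Cntfr (0.851), Nfe2l2 (0.875), Gata4 (0.841), Folr2 (0.940), Bmp2 (0.905), Stab2 (0.905), Dab2 (0.851) and the sinusoidal endothelial score (0.878), and its endothelial score was 6.69 against 7.74 to 7.88. In wild type library 1 at 9 weeks they were those of Ccl2 (0.859), Scd2 (0.838), S100a8 (0.831), Ldha (0.868), Lcn2 (0.860) and the neutrophil score (0.926). Elsewhere they were the immediate early and heat shock score (0.838) in ob/ob library 1 at 14 weeks, Gpnmb (0.867) in ob/ob library 4 at 14 weeks, Retnlg (0.945) in wild type library 2 at 14 weeks, Me1 (0.900), Ifi27l2a (0.914) and Fcgrt (0.879) in wild type library 3 at 14 weeks, Retnla (0.922) and Fcmr (0.897) in wild type library 4 at 14 weeks, Txnrd1 (0.876), Hbb-bs (0.951) and the unfolded protein response score (0.888) in wild type library 2 at 9 weeks, Apoa2 (0.935) and Cd63 (0.885) in wild type library 3 at 9 weeks and Col3a1 (0.916) in wild type library 4 at 9 weeks.

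The ob/ob effect of 13 lists differed between the ages by camera, relative to all genes, given here as the median log2 difference, 14 minus 9 weeks, the number of members above 0 and the adjusted p. Placed higher at 14 weeks were antioxidant enzymes outside the NRF2 list (0.084, 19 of 29 above 0, 0.0262), type I interferon response (0.21, 28 of 30 above 0, 4.6e-05), lipid uptake and storage (0.13, 12 of 19 above 0, 0.0262), fatty acid oxidation (0.069, 13 of 22 above 0, 0.0395), lysosome (0.075, 26 of 35 above 0, 0.00586), lipid-associated macrophage (0.12, 17 of 20 above 0, 0.0298), dendritic cell (0.27, 10 of 14 above 0, 0.0262), T and NK cell (0.46, 11 of 12 above 0, 0.00294), sinusoidal endothelial (0.39, 19 of 20 above 0, 0.00283) and hepatic stellate cell (0.43, 10 of 11 above 0, 0.00294). Placed lower were immediate early and heat shock genes (-0.37, 5 of 25 above 0, 0.0156), neutrophil (-0.31, 1 of 13 above 0, 0.0362) and hepatocyte (-0.37, 5 of 33 above 0, 0.0316). With an estimated correlation none of the 13 passed (adjusted p = 0.846 to 0.906), so these differences rest on the preset correlation.

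Hepatocyte transcripts were higher in ob/ob at both ages, with list medians of 2.24 and 1.75 on the log2 scale, and of its abundant genes Alb was 10.7- and 7.32-fold, Ttr 13.6- and 7.97-fold and Apoa1 4.68- and 3.28-fold higher; camera's calls (adjusted p = 1.9e-27 and 9.4e-19) were lost with an estimated correlation (0.234 and 0.264). Library scaling was argued against, since under median-ratio scaling the list median was at least 1.02 times that of the deposited values at both ages. Hepatocyte RNA carried into the preparation needs the list's genes to vary together between libraries of a group, and they did, with a median pairwise correlation of 0.732 over 33 members, so it is a candidate source, and the labels name no sort or gate that would remove it. Of 33 list genes in the tables, 30 had a mean of at least 1 FPKM in wild type libraries and 3 were also on another list. More hepatocyte RNA of the same make-up would raise its genes alike. With the hepatocyte score in a joint fit, though, 22 genes passed at 9 weeks (16 higher) and 110 at 14 weeks (74 higher). Among them were Mup20 (-4.07 ± 0.57 and -3.27 ± 0.49) and Mup3 (-3.22 ± 0.51 and -3.10 ± 0.44), with near-identical copies, and Apoa4 (5.06 ± 0.48 and 4.73 ± 0.41). For these genes such RNA alone is argued against. How much of the list's difference came from more hepatocyte RNA per library and how much from expression that differs with genotype was not tested, and lane cannot be told apart from group.

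Genes of lipid-associated macrophages were higher in ob/ob, with list medians of 0.60 and 0.75 on the log2 scale; camera's call held with an estimated correlation at 9 weeks (adjusted p = 0.0444) and was lost at 14 weeks (0.151). Hepatocyte RNA and library scaling were argued against: within groups the list score changed by -0.132 per unit of the hepatocyte score (95% interval -0.283 to 0.0192), below the 0.297 that 0.5 of the ob/ob change would need, and under median-ratio scaling the list median was at least 1.08 times that of the deposited values. A smaller share of other cell types would raise Kupffer cell genes alike, but the lipid-associated minus the Kupffer cell score was higher in each ob/ob library than in each wild type library of its age, by 1.25 and 1.44 (exact permutation p = 0.0286 at either age, the smallest that these splits can give). Of 20 list genes, 18 had a mean of at least 1 FPKM in wild type libraries and 5 were also on another list. Open are recruited monocyte-derived cells, since 10 of 20 genes of their list rose at 9 weeks, a change of resident cells with obesity, which was not tested, and the lane of each group.

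NRF2 target genes were placed higher in ob/ob by camera, with list medians of 0.089 and 0.055 on the log2 scale; the calls (adjusted p = 0.0340 and 0.0292) were lost with an estimated correlation (0.478 and 0.478). Hepatocyte RNA is a candidate explanation, since within groups the list score rose by 0.149 per unit of the hepatocyte score (95% interval 0.0927 to 0.206), and 0.0586 would give 0.5 of the ob/ob change. A slope of 0.117, inside that interval, would give all of it. Library scaling cannot be told apart: under median-ratio scaling the call ended at 9 weeks (adjusted p = 0.0507) and stayed at 14 weeks (0.0497), both close to the threshold, and the list medians, 0.14 (quartiles -0.14 and 0.38, as deposited -0.19 and 0.33) and 0.14 (quartiles -0.083 and 0.44, as deposited -0.17 and 0.35), decide nothing, since they moved with the median of all genes (from -0.057 to -0.010 and from -0.091 to -0.015) and 20 of 37 and 20 of 36 members lay above 0 as deposited. Of 37 list genes, 34 had a mean of at least 1 FPKM in wild type libraries and 5 were also on another list. A change of NRF2 activity in the Kupffer cells of ob/ob mice stays open and was not tested.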

How the results depend on the processing

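The endothelial score as a covariate, the hepatocyte score in a joint fit and the 2 settings that leave out a pair of libraries were chosen after the data were seen. At 9 weeks the count of 909 genes stood between 827 and 1235 under a pseudocount of 0.1, no filter on low values, median-ratio scaling, quantile normalization, robust eBayes and library weights. It was 528 with a filter at a mean of 5 FPKM, where 8166 genes were tested, 278 with replicate number as a block, 1400 in a joint fit, 496 with the endothelial score as a covariate, 22 with the hepatocyte score in a joint fit, and 356 without ob/ob libraries 1 and 3, where the lone ob/ob library is assumed to vary like the wild type ones. With the hepatocyte score as a covariate limma called 0, with 598 below an unadjusted p of 0.05. At 14 weeks 1548 became 1288 to 2107 under a pseudocount of 0.1, no filter on low values, median-ratio scaling, quantile normalization, robust eBayes, a joint fit of all libraries and leaving out ob/ob library 2 and wild type library 1 together, 927 of 8230 tested with the filter at 5, 512 with the block, 2580 with library weights, 2657 with the endothelial score, 9 with the hepatocyte score and 110 with it in a joint fit. Leaving out 1 library gave 409 (without ob/ob library 1) to 901 at 9 weeks and 942 (without wild type library 4) to 1786 at 14 weeks. Fewer genes were tested under the filter and fewer libraries when some were left out, and of the other changes of these counts the cause was not tested, except for the hepatocyte score. 93.3% of its variance at 9 weeks and 73.5% at 14 weeks lay between the genotypes, and the median standard error grew 3.75- and 1.96-fold. The Gpnmb log2 change at 9 weeks was 4.97 ± 0.28 without and 6.97 ± 0.87 with that score (adjusted p = 0.208), a call that ended as its error grew. The replicate numbers are not known to pair libraries, with correlations of -0.474 to 0.110 between the deviations of equal numbers and no library whose best match had its own number.

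Lists called numbered 17 at 9 weeks and 22 at 14 weeks, and 15 to 19 and 19 to 23 without 1 library. With the block they numbered 17 and 23, with adjusted p = 0.0129 for Kupffer cell identity and 0.0544 for NRF2 target genes at 9 weeks, 0.0310 for type I interferon response at 14 weeks, and the same side of the threshold as without the block for the other lists. With an estimated correlation camera called 1 and 0, with 5 and 5 below an unadjusted p of 0.05, and the cause was not tested. The Pearson r of the changes between the ages was 0.818 to 0.885 without 1 library and 0.822 without ob/ob libraries 1 and 3, and the count of genes called the same way at both was 317 to 624, 312 and, with the filter at 5, 333. For the difference between ages limma called 0 to 3 genes without 1 library, 1 without ob/ob libraries 1 and 3 at 9 weeks, and 0 in each other setting (294 to 751 below an unadjusted p of 0.05). Each of the 35 splits of the 9 week libraries was fitted: 1 split, the real, gave as many as 909 genes, and the highest other gave 3. At 14 weeks 1 of 35 splits gave as many as 1548, and the highest other gave 1. A share of 1 in 35 is the smallest that these splits can give, so they do not exclude chance at either age. Lane followed group, so the splits cannot tell genotype from lane. For the difference between ages the real split gave 0, a count that 100 of 100 splits meet whatever the data, so the splits say nothing of chance there. The highest other gave 152, in a split that left the 9 week groups as they are and, at 14 weeks, put ob/ob library 4 with wild type libraries 1, 2 and 3.

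Of the gene values named in the text, 1236 of 1504 kept their direction and side of the threshold without 1 library, 179 of 200 did under median-ratio scaling, 198 with a pseudocount of 0.1, 123 with the block, 149 with the endothelial score and 29 with the hepatocyte score. The sign of the log2 change turned under median-ratio scaling for Nfe2l2 (0.049) and Gclm (0.038) at 9 weeks and Nfe2l2 (0.039) and Gclm (0.043) at 14 weeks, under quantile normalization for Nfe2l2 (0.089) and Gclm (0.084) at 9 weeks and Nfe2l2 (0.0026) and Gclm (0.034) at 14 weeks, with library weights for Nfe2l2 (0.0074) at 9 weeks and Nfe2l2 (0.0028) at 14 weeks, with the hepatocyte score as a covariate for Cd209f (0.94), Gclm (0.059), Txnrd1 (-0.29), Srxn1 (-0.93), Tnf (-0.045), Gata4 (0.56), Lepr (0.46), Selenop (0.17), Hamp (-0.47), Bst2 (0.37) and Dab2 (0.73) at 9 weeks and Gclc (-0.33), Hamp (-0.18) and Krt18 (-0.19) at 14 weeks, with the endothelial score for Txnrd1 (-0.037), Srxn1 (-0.063), Gata4 (0.45) and Lepr (0.24) at 9 weeks and Txnrd1 (-0.019) and Gata4 (0.15) at 14 weeks, with the hepatocyte score in a joint fit for Gclc (-0.28), Srxn1 (-0.22), Tnf (-0.38), Il1b (-0.0041), Lepr (0.21), Gsta3 (-0.51), Selenow (0.047) and Hamp (-0.0032) at 9 weeks and Gclc (-0.23), Hamp (-0.28) and Krt18 (-0.039) at 14 weeks, without ob/ob libraries 1 and 3 for Nfe2l2 (0.045) and Srxn1 (-0.032) at 9 weeks and without ob/ob library 2 and wild type library 1 for Nfe2l2 (0.022) at 14 weeks. Without 1 library it turned in some fits for Nfe2l2 at 9 weeks (-0.038 to 0.070), Gclm at 9 weeks (-0.092 to 0.048), Nfe2l2 at 14 weeks (-0.076 to 0.025), Gclc at 14 weeks (-0.014 to 0.12) and Gclm at 14 weeks (-0.12 to 0.030). The cause of these turns was not tested, and Hamp is itself part of the hepatocyte score. Read depth, which is unknown, limits genes of low FPKM, whose changes on this scale are understated.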

Other observations

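The genes of this paragraph, on none of the lists, and the test of the X chromosome segment below were chosen after their values were seen. At 9 and 14 weeks, the chemokine gene Ccl9 rose by 2.44 ± 0.21 and 2.93 ± 0.22 on the log2 scale, and Ccr1, which encodes a receptor for its product, rose by 2.16 ± 0.29 and 1.76 ± 0.22. Clec4e, a receptor of macrophages for glycolipids of mycobacteria and for dying cells, rose by 2.29 ± 0.14 and 1.83 ± 0.26. Fcna, a ficolin of the lectin pathway of complement, fell by 0.87 ± 0.19 at 9 weeks and fell also at 14 weeks, the endocytic adaptor gene Dab2 fell by 0.91 ± 0.21 and 0.81 ± 0.15, and Fcgrt, the receptor that recycles immunoglobulin G and albumin, fell by 0.77 ± 0.092 and 0.77 ± 0.087. Txnip, a glucose-induced inhibitor of thioredoxin, fell by 0.71 ± 0.16 and 0.74 ± 0.13. Each of these passed the test at both ages. With the hepatocyte score as a covariate the change of Dab2 at 9 weeks turned to 0.73 ± 0.57 and did not pass (adjusted p = 0.910).

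Neighbouring genes on the X chromosome, from 166238911 to 169320372 on GRCm38, stood higher in ob/ob libraries 1 and 3 at 9 weeks. Over the 8 with a mean of at least 5 FPKM, Gpm6b, Rab9, Tmsb4x, Tlr8, Tlr7, Prps2, Msl3 and Hccs, the median log2 ratio to the wild type mean was 0.79 and 1.10, with 8 of 8 above 0.5 in either library. It was 0.012 in ob/ob library 4, -0.095 to 0.12 in wild type libraries of that age and -0.10 to 0.18 in libraries at 14 weeks. The 11 tested genes beside the segment, Mospd2 before it and Mid1 after it among them, had medians of -0.10 and 0.085 in the same libraries. A candidate explanation is a further copy of the segment in those animals, which would give about 1 log2 unit with no change beside it, and a segment with Tlr7 copied to the Y chromosome is known from mice with the Yaa variant. Expression cannot place such a copy, and a regulatory change of the whole segment was not tested. All chromosomes were scanned in 7568 windows of 10 neighbouring genes, as log2 against the median library at 9 weeks. The largest windows of ob/ob libraries 1 and 3 were on chromosome 5 (0.97 and 1.35), above their largest X windows (0.65 and 0.92). Windows beyond 0.5 in either direction numbered 17 and 14, so the X segment was not the only run of genes that stood apart. The chromosome 5 window of library 3, Ythdc1 to Gc, was also the largest of ob/ob library 4 (0.85), whose largest X window was 0.14. A chromosome 5 run was thus shared by the ob/ob libraries of that age, and the X run was not.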
